A study of Equus caballus with 93 samples.

How the data were processed

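Cells were collected by centrifugation from synovial fluid of horses whose middle carpal joint had been operated on to produce an osteochondral fragment, a surgical model of osteoarthritis, and their total RNA was sequenced after library preparation with a stranded low-input total RNA kit, per the labels' protocols. The labels and design text describe 16 horses, 8 per arm, which received 2 mL of either 2.5% injectable polyacrylamide hydrogel (iPAAG) or saline (Control) in the operated joint at week 2 and were exercised from week 2 to week 10. The 6 sampling times were weeks 0, 2, 4, 6, 8 and 10. Week 0 preceded surgery, per the labels' protocols. The labels do not say whether the week 2 fluid was drawn before or after the injection. Surgery, elapsed time and, from week 2, exercise change together in both arms, so a change over weeks does not separate them. The sham-operated joints and the synovial membrane samples named in the design text were not analysed here.

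The authors deposited 1 table of log2 values for 15838 genes in 93 libraries, named there as normalised log2 CPM (reads relative to library size) from voom. The submitters' processing notes name the aligner STAR 2.7.10b, the horse genome build EquCab3.0 and limma 3.62.2. The read counting, the use of strand in counting, the annotation release and the filter on low genes are not given in the sources used here. Where genes overlap or have near-identical copies, the share of reads each received is therefore uncertain. The deposited log2 values are whole reads plus 0.5 divided by a scaled library size. The smallest value of each library gives what 1 read is worth, and on that scale 100.0% of the values were whole reads within a tolerance of 0.05 reads. The recovered reads in genes ranged from 1737741 to 39916655 per library, with a median of 21063527, and the factor between scaled and counted library size ranged from 0.40 to 2.49. A gene with few reads is dominated by the added 0.5 reads, so its log2 change can understate a change. With no reads in either of a pair of libraries, it gets the higher log2 value in the library of smaller scaled size. Both matter most in the shallow libraries. These are PCR-amplified reads, not counted molecules.

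The table names genes by Ensembl horse identifiers without symbols. The table of gene names used here, from another horse assembly, paired 0 of the 15838 identifiers with a name. The files do not pair identifiers with names, so the 25 gene lists fixed for pathways and cell types could not be tested and 0 list tests were run. Before the data were examined, the rule for named genes was set as the largest rises and falls among genes with a symbol, an adjusted p below 0.05, a mean log2 CPM of at least 1 and the fitted sign in at least 75% of the horses compared. Because no gene had a symbol, the rule was applied without that condition, and the 2 largest rises and the 2 largest falls from week 0 to week 2 are given by identifier and followed in the other comparisons.

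Each library was assigned to its arm, horse and week from its label. The 13 horses with all 6 weeks contributed 6 libraries each, and 3 libraries were missing from the other horses: horses 03 and 11 at week 4 and horse 14 at week 8. No pair of libraries within a group was identical, and the smallest chi-square per degree of freedom between any pair was 9.44 over genes with at least 10 reads, so every library was kept as a separate sample. The libraries of 1 horse come from the same animal. The mean correlation of deviations from the group means was 0.06 for pairs of libraries from the same horse and -0.01 for pairs from different horses in different groups. After the part that follows library spread was removed, the value for the same horse was 0.11.

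Tests used limma 3.58.1 in R 4.3.3. A linear model with 12 arm-by-week means was fitted to the deposited log2 values of all 93 libraries. Horse entered as a random block through duplicateCorrelation, with a consensus correlation of 0.04, because the design samples the same animals repeatedly. Variances were moderated with a mean-variance trend, and p-values were adjusted by Benjamini-Hochberg over all genes of a contrast, with a threshold of 0.05. A gene past it is described as called. Standard errors (SE) are those of limma. Values per library were compared between arms by two-sided exact permutation tests, with Benjamini-Hochberg adjustment within each family. Library spread is the SD over all genes of a library's log2 CPM. The number of genes detected at a common depth is the number expected in a random draw of 1737741 reads. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for these values and the plots.

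The model was tested on simulated reads of all 15838 genes, drawn from a single mean profile with a horse effect and the real library sizes. No set of libraries of low spread was simulated, so the false calls below do not give the error rate in the deposited values. For week 2 against week 0, 80 of 100 genes changed by 2-fold and 100 of 100 changed by 4-fold were recovered, with 3 false calls. For the treatment difference in change from week 2 to weeks 4 to 10, 16 of 100 genes changed by 2-fold and 92 of 100 changed by 4-fold were recovered, with 7 false calls. When a known change was instead added to 200 genes of the deposited values in the iPAAG libraries of weeks 4 to 10, the same treatment contrast recovered 90 of them at 2-fold and 151 at 4-fold.

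Alternatives fixed beforehand were no horse block, horse as a fixed term, quantile normalisation, centring on library medians, filters on low genes, other variance models, library weights, voom precision weights on the recovered reads, fits restricted to the groups compared, fits restricted to the 13 complete horses, each horse left out in turn, and other summaries of the treatment difference. Added after seeing the data were fits without the 23 libraries of spread below 2, without the 34 libraries of spread below 3, with library spread as a covariate, and without the Control library of horse 11 at week 8.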

Results

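Gene expression was measured by RNA sequencing in synovial fluid cells of 16 horses with a surgically induced osteochondral fragment in a middle carpal joint. The joint received saline (Control, 8 horses) or iPAAG, a polyacrylamide hydrogel (8 horses), at week 2. Fluid was sampled at weeks 0, 2, 4, 6, 8 and 10, which gave 93 libraries in 12 groups. There were 8 libraries per group, except for 7 in each arm at week 4 and 7 in the iPAAG arm at week 8. Reads in genes averaged 27912001 ± 4890213 (SD, n = 8) in Control and 27509691 ± 7973007 (SD, n = 8) in iPAAG horses at week 0. By week 10 they averaged 19490526 ± 8488988 (SD, n = 8) in Control and 10329101 ± 7727503 (SD, n = 8) in iPAAG horses. The shallowest library, iPAAG horse 17 at week 10, held 1737741 reads.

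The libraries differed in how widely expression values were spread over genes. The SD of log2 CPM within a library ranged from 1.20 to 4.21, and the first principal component of all values held 65.7% of the variance. Across libraries, that component had an absolute Pearson r of 0.998 with library spread. Spread was below 2 in 23 libraries from 12 horses, and no library lay between 1.90 and 2.19. Of these libraries, 6 were from Control horses, at weeks 2, 6, 8 and 10. The iPAAG arm had 1 at week 0, 1 at week 2, 4 of 7 at week 4, 4 of 8 at week 6, 1 of 7 at week 8 and 6 of 8 at week 10. These libraries held 1737741 to 12597216 reads, and between 3 and 65 of the 15838 genes had no read in them. Mean spread was already lower in the iPAAG arm at week 0, at 3.07 against 3.53 in Control horses (8 horses each, exact permutation p = 0.0418, adjusted p = 0.136). At week 4 it was 2.33 ± 1.26 (SD, n = 7) in iPAAG and 3.47 ± 0.25 (SD, n = 7) in Control horses, which did not pass a two-sided exact permutation test (p = 0.0682, adjusted p = 0.136 over 8 comparisons). At week 10 the means were 1.99 ± 0.94 (SD, n = 8) and 2.97 ± 0.90 (SD, n = 8), with exact permutation p = 0.0564 and adjusted p = 0.136. The change in spread from week 2 to the mean of weeks 4 to 10 was -0.50 in iPAAG and -0.18 in Control horses (8 horses each, exact permutation p = 0.548). The mean over weeks 4 to 10 itself was 2.48 in iPAAG and 3.06 in Control horses (exact permutation p = 0.0368, adjusted p = 0.136).

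**Figure D1:**
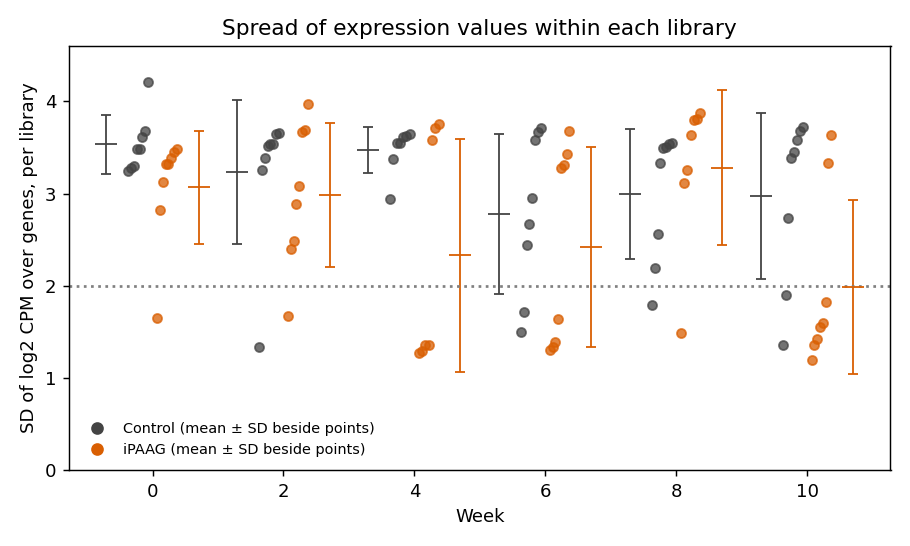
Spread of expression values in each library: the horizontal axis is the week and the vertical axis the SD over genes of log2 CPM. Points are libraries of Control (grey) and iPAAG (orange) horses, bars beside them are mean ± SD, and the dotted line marks 2, below which 23 of the 93 libraries lie, 6 of them in the iPAAG group of week 10.

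The first comparison asked how the cells changed between the sample before surgery and week 2, with both arms together. ENSECAG00000007588 rose by 7.32 ± 0.62 on the log2 scale (SE, adjusted p = 6.69e-16), from a mean log2 CPM of -2.26 ± 2.72 (SD, n = 16) to 5.06 ± 1.53 (SD, n = 16), and was higher in 16 of 16 horses. ENSECAG00000022525 rose by 6.37 ± 0.58 (SE, adjusted p = 1.2e-14), also in 16 of 16 horses. ENSECAG00000023772 fell by 4.18 ± 0.46 (SE, adjusted p = 2.32e-11), from 9.19 ± 1.41 to 5.01 ± 1.42 (SD, n = 16), with a fall in 16 of 16 horses. ENSECAG00000018814 fell by 4.54 ± 0.84 (SE, adjusted p = 2.07e-05), with a fall in 15 of 16 horses. At week 0, ENSECAG00000007588 had a median of 5.5 reads and no read in 4 of the 16 libraries, and ENSECAG00000022525 had a median of 11 reads and no read in 2, so the size of both rises depends on the 0.5 reads added to each count.

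Across all 15838 genes, 3112 were called between week 0 and week 2, 1321 higher and 1791 lower. Among the called genes, 137 were higher and 218 lower in every horse. Without the 23 libraries of spread below 2 the count was 6362 genes, 3334 higher and 3028 lower. Centring each library on its median changed the split from 42.4% higher to 55.9% higher, with 1481 genes higher and 1169 lower.

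**Figure D2:**
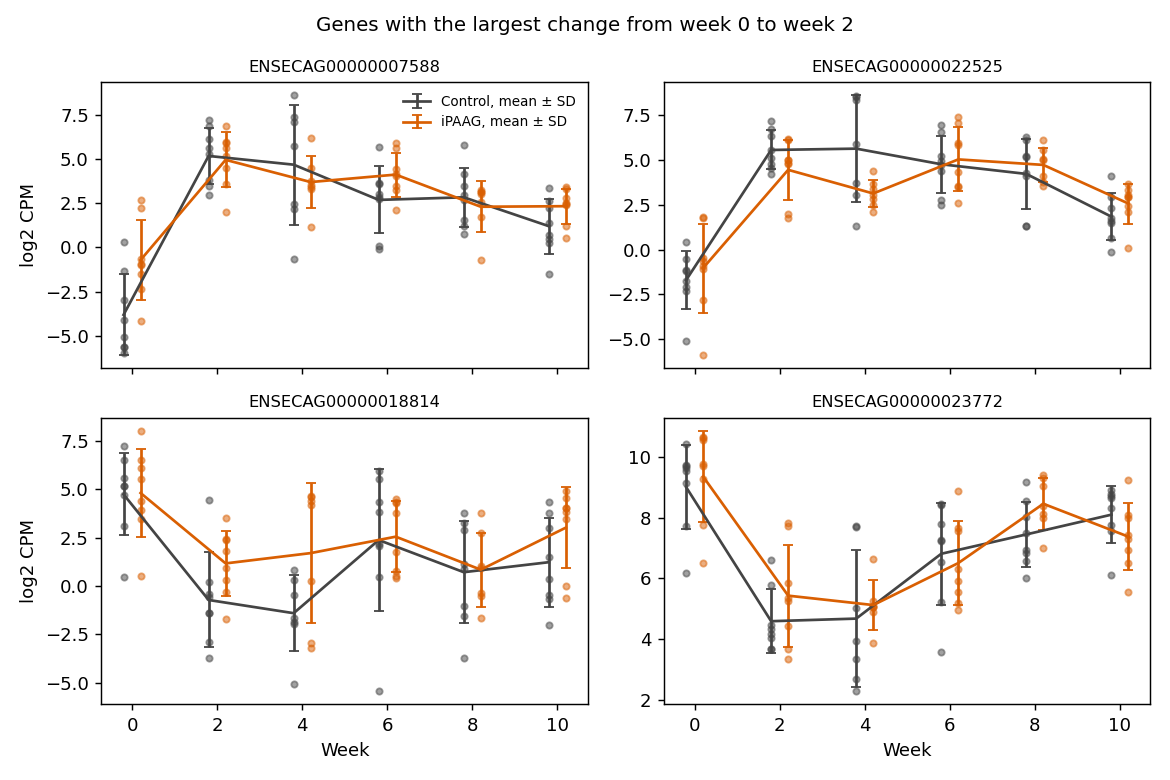
Deposited log2 CPM of 4 genes by week: each panel is a gene, points are libraries, and lines join the mean ± SD of Control (grey) and iPAAG (orange) horses. The upper genes rose in 16 of 16 horses from week 0 to week 2, and the lower genes fell in 15 and 16 of 16.

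Each arm was also tested alone at week 2, although the labels do not say whether that fluid was drawn before the injection. In Control horses 1030 genes were called at week 2 against week 0, and in iPAAG horses 1579. The Control count was 450 without horse 15 and 521 without horse 11, and the iPAAG count 914 without horse 6 and 980 without horse 7. Without the libraries of spread below 2 the counts were 3216 and 4289. The arms share no library, so genes called in 1 arm were measured in the other. Of the 610 genes higher in Control horses, 607 were also higher in iPAAG horses, with a median log2 change of 1.26, and 309 were called there, where 23.3 would be shared by independent lists. Of the 420 genes lower in Control horses, 420 were lower in iPAAG horses, with a median of -1.02, and 298 were called, against 25.8 for independent lists. The arms share a variance estimate per gene, so more overlap than in independent lists can arise without a shared change. Across genes, which are not independent replicates, the week 2 changes of the 2 arms had a Pearson r of 0.71 and a Spearman rho of 0.67. The difference between arms in this change was called for 0 genes by limma, with 206 genes at an unadjusted p below 0.05.

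The same genes were followed at later weeks in the arm in which they had not been selected. Genes higher at week 2 in Control horses had a median log2 change from week 0 in iPAAG horses of 0.86 at week 4, 0.98 at week 6, 0.45 at week 8 and 0.66 at week 10. The share with a rise was 88.0% at week 4, 94.6% at week 6, 70.3% at week 8 and 76.1% at week 10. Genes lower at week 2 in Control horses had a median of -0.82 at week 4, -0.68 at week 6, -0.38 at week 8 and -0.53 at week 10 in iPAAG horses, with a fall in 92.4%, 96.0%, 73.3% and 84.3% of them. In the other direction, the 605 genes higher at week 2 in iPAAG horses had a median in Control horses of 0.99 at week 2, 0.83 at week 4, 0.58 at week 6, 0.41 at week 8 and 0.60 at week 10. Of these, 84.6% were higher at week 8 and 92.6% at week 10. The 974 genes lower at week 2 in iPAAG horses had a median of -0.75 at week 2, -0.50 at week 4, -0.57 at week 6, -0.36 at week 8 and -0.68 at week 10, with 81.0% lower at week 8 and 87.6% at week 10. The differences between weeks in these medians were not tested. Without the libraries of spread below 2, the medians in iPAAG horses of the 1996 genes then higher in Control horses at week 2 were 0.36, 0.45, 0.31 and 0.29 at weeks 4 to 10, and those of the 1220 lower genes -0.70, -0.54, -0.41 and -0.39. In that fit the medians in Control horses were 0.39, 0.37, 0.25 and 0.40 for the 2220 genes higher in iPAAG horses and -0.45, -0.43, -0.30 and -0.57 for the 2069 lower. That fit kept 3 iPAAG libraries at week 4 and 2 at week 10. With all libraries, 60.2% of all 15838 genes were lower at week 8 in iPAAG horses, beside the 73.3%, and 39.8% were higher, beside the 70.3%.

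**Figure D3:**
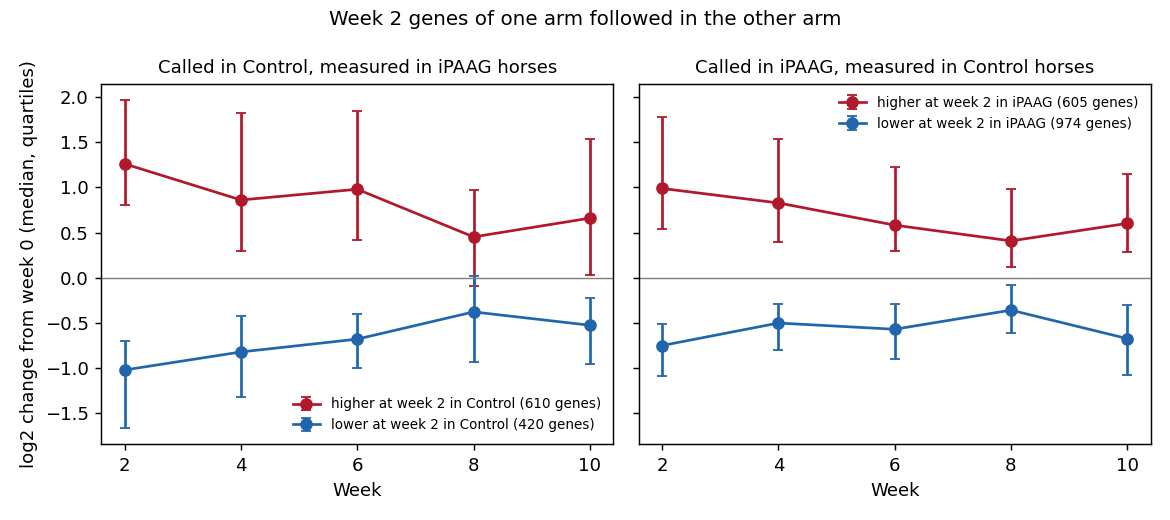
Genes called at week 2 in 1 arm, measured in the other arm: the horizontal axis is the week and the vertical axis the log2 change from week 0. Points are medians over genes and bars run from the lower to the upper quartile. In iPAAG horses the medians of the genes selected in Control horses were 1.26 and -1.02 at week 2 and 0.66 and -0.53 at week 10.

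Weeks 4 to 10 were then compared with week 0 over both arms. ENSECAG00000022525 remained higher by 5.36 ± 0.46 on the log2 scale (SE, adjusted p = 1.86e-15) and ENSECAG00000007588 by 5.25 ± 0.49 (SE, adjusted p = 1.16e-13), each in 16 of 16 horses. ENSECAG00000018814 fell by 3.39 ± 0.67 (SE, adjusted p = 4.94e-05) and ENSECAG00000023772 fell by 2.38 ± 0.36 (SE, adjusted p = 5.36e-07), each in 15 of 16 horses. In total 5422 genes were called, 2097 higher and 3325 lower. That is 38.7% higher, which became 46.8% with median centring (2168 higher and 2467 lower), 25.7% among genes with a mean log2 CPM of at least 1 (1158 and 3342) and 23.1% with voom weights (872 and 2899). Among the called genes 80 were higher and 357 lower in every horse. Without the 23 libraries of spread below 2 the fit called 6178 genes, 2591 higher and 3587 lower. With all libraries, 1458 called genes were higher and 266 lower by 1 or more on the log2 scale. Without those 23 libraries, 479 were higher and 832 lower by that much. Across all genes, the changes with all libraries had a Pearson r of -0.785 with each gene's slope on library spread in Control horses. Without the 23 libraries r was 0.03, so with all libraries the changes went in part with library spread.

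By single week, 613 genes were called at week 4 against week 0 in Control horses, 1188 at week 6, 469 at week 8 and 1551 at week 10. In iPAAG horses the counts were 5206 at week 4, 1301 at week 6, 1263 at week 8 and 5866 at week 10, and 9346 genes were called in at least 1 of the 10 single-week contrasts against week 0. Of the iPAAG libraries, 4 of 7 at week 4, 4 of 8 at week 6, 1 of 7 at week 8 and 6 of 8 at week 10 had a spread below 2, so weeks 6 and 8 had similar counts with different numbers of such libraries. Without those libraries the iPAAG counts were 860 at week 4, 672 at week 6, 4518 at week 8 and 828 at week 10, with 3, 4, 6 and 2 libraries left at these weeks. Single horses also moved the counts. In iPAAG horses, week 4 gave 1936, 2650 and 2982 genes without horses 7, 5 and 6. Week 6 gave 122, 156, 289 and 496 without horses 6, 7, 8 and 17, and 2181, 2671 and 5537 without horses 5, 3 and 14. Week 8 gave 442, 467 and 524 without horses 6, 12 and 5, and 1913 without horse 3. Week 10 gave 2586, 2626, 2696, 2870 and 2966 without horses 12, 3, 6, 17 and 7, and 9948 without horse 14. In Control horses, week 4 gave 243, 244 and 369 without horses 16, 15 and 2. Week 6 gave 478, 537, 588, 675, 697 and 705 without horses 9, 13, 15, 16, 2 and 10. Week 8 gave 155, 208, 231 and 245 without horses 11, 9, 13 and 2.

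Against week 2, 1 gene was called at week 4 in Control horses, 529 at week 6, 338 at week 8 and 1232 at week 10. In iPAAG horses 6306 genes were called at week 4 against week 2, 2394 at week 6, 536 at week 8 and 7492 at week 10, and 9626 genes were called in at least 1 of these contrasts. Without the libraries of spread below 2 the iPAAG counts against week 2 were 31, 160, 1957 and 10. With 1 horse left out, iPAAG week 4 gave 2338, 3401 and 3993 without horses 7, 5 and 6. Week 6 gave 21, 34, 63 and 977 without horses 7, 6, 8 and 17, and 4293 and 7502 without horses 12 and 14. Week 8 gave 159, 230 and 315 without horses 5, 6 and 7, and week 10 gave 2720, 3325 and 4946 without horses 3, 7 and 6 and 11541 without horse 14. In Control horses, week 4 gave 0 without any of 10 horses. Week 6 gave 64, 216, 252 and 253 without horses 15, 16, 2 and 13, and 1172 without horse 10. Week 8 gave 43, 148 and 166 without horses 15, 2 and 13, and week 10 gave 573, 714 and 778 without horses 15, 2 and 16 and 2380 without horse 10.

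At week 10 the 2 arms were compared with their own week 0 samples. ENSECAG00000007588 was higher by 5.01 ± 0.88 (SE, adjusted p = 0.00018) in 8 of 8 Control horses and by 3.04 ± 0.88 (SE, adjusted p = 0.00835) in 7 of 8 iPAAG horses. Its mean log2 CPM at week 0 was -3.81 ± 2.30 in Control and -0.72 ± 2.26 in iPAAG horses (SD, n = 8). At week 10 the means were 1.20 ± 1.56 and 2.33 ± 0.99 (SD, n = 8). The smaller rise in iPAAG horses thus started from a higher week 0 mean and did not end at a lower week 10 mean. ENSECAG00000022525 was higher by 3.54 ± 0.82 (SE, adjusted p = 0.00276) in 7 of 8 Control horses and by 3.60 ± 0.82 (SE, adjusted p = 0.0015) in 8 of 8 iPAAG horses. With voom weights none of these 4 calls remained, with changes of 4.69 ± 3.52 and 2.96 ± 2.26 for ENSECAG00000007588 and 3.25 ± 2.80 and 3.64 ± 2.40 for ENSECAG00000022525 (SE, adjusted p = 0.497, 0.278, 0.579 and 0.209), so they ended through larger SEs. Quantile normalisation ended 3 of them with smaller changes: ENSECAG00000007588 in iPAAG horses went to 1.31 ± 0.86 (SE, adjusted p = 0.197), and ENSECAG00000022525 to 2.42 ± 0.84 (SE, adjusted p = 0.0691) in Control and 1.44 ± 0.84 (SE, adjusted p = 0.146) in iPAAG horses.

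For the genes that fell at week 2, ENSECAG00000018814 changed by week 10 by -3.50 ± 1.18 (SE, adjusted p = 0.0445) in Control horses, a call near the threshold. It was lost with horse as a fixed block (adjusted p = 0.0508), without a block (0.0517), with voom weights (0.0692) and without horse 1, 2, 8, 9, 10, 11, 15 or 16 (0.0524 to 0.109). In iPAAG horses this gene had a value of -1.79 ± 1.18 (SE, adjusted p = 0.202), which became -4.83 ± 1.71 (SE, adjusted p = 0.0748) without the libraries of spread below 2 and -3.99 ± 0.90 (SE, adjusted p = 0.00514) with spread as a covariate. ENSECAG00000023772 had a value of -0.91 ± 0.65 (SE, adjusted p = 0.394) in Control horses and changed by -1.98 ± 0.65 (SE, adjusted p = 0.0169) in iPAAG horses, or by -1.53 without horse 3 (adjusted p = 0.0879). That call was also lost with quantile normalisation (-1.05, adjusted p = 0.143), in the 13 horses with all 6 weeks (-1.40, 0.0885), with voom weights (-1.88, 0.106), with the groups compared alone (-1.98, 0.0582) and with spread as a covariate (-1.93, 0.0559).

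Without the libraries of spread below 2, which left 2 iPAAG libraries at week 10, the 3 genes called there in iPAAG horses were no longer called. The change of ENSECAG00000022525 was then 3.15 ± 1.38 (SE, adjusted p = 0.149), so the call ended through a larger SE with little change in size. ENSECAG00000007588 went to 1.85 ± 1.49 (SE, adjusted p = 0.483) and ENSECAG00000023772 to -1.17 ± 1.14 (SE, adjusted p = 0.576), each with a smaller change and a larger SE. Without spread below 3 the 3 values were 3.19, 1.80 and -0.92 (adjusted p = 0.125, 0.505 and 0.635).

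In Control horses 1551 genes were called at week 10 against week 0, 496 higher and 1055 lower, and 3538 without the libraries of spread below 2. Across all genes, these changes had a Pearson r of -0.636 with each gene's slope on library spread in Control horses. Without those libraries r was -0.09. Centring on library medians moved the Control split from 32.0% higher to 43.4% higher. Leaving out horse 13 gave 710 genes and leaving out horse 9 gave 841. In iPAAG horses 5866 genes were called, 2196 higher and 3670 lower, and 828 without the libraries of spread below 2. The iPAAG split of 37.4% higher became 17.2% with spread as a covariate (182 higher and 876 lower) and 49.5% with array weights (6253 and 6388). The difference between the arms in this change was called for 0 genes by limma, with all libraries and without those of spread below 2, so the larger count in iPAAG horses was not shown to be a difference between the arms.

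The treatment question was addressed by the arms' difference in change from week 2, the week of injection, to weeks 4 to 10. No gene was called by limma (0 of 15838, with 3765 at an unadjusted p below 0.05), and 0 were called without the 23 libraries of spread below 2, where 1682 had an unadjusted p below 0.05. That count depends on the model: 2358 genes were called with spread as a covariate, 257 higher and 2101 lower in iPAAG horses, 10320 with array weights, and 2903 without horse 14. By single week, 3633 genes differed in the change from week 2 to week 4, 389 higher and 3244 lower in iPAAG horses, and 0 genes at weeks 6, 8 and 10. The split depends on the scaling: over these 4 weeks together 10.7% of the called genes were higher, and 33.4% with quantile normalisation (1649 higher and 3288 lower). Without horse 14, 1188 genes were called at week 6 and 4885 at week 10, and without horse 9 the counts were 60 and 3. The week 4 count was 2 without the libraries of spread below 2 and 0 when only the groups compared were fitted. It was also 0 when horse 5, 6, 7 or 10 was left out. It was 2345 without horse 16 and 5666 without horse 12. At week 6, 144 genes were called without the libraries of spread below 2, 124 of them higher. Without those of spread below 3, 163 genes were called at week 6, 158 of them higher. Few libraries remained there: at week 6, 4 of 8 iPAAG libraries had a spread below 2, and 5 of 8 Control libraries a spread below 3. The differences in the fit without spread below 2 were also compared across genes with each gene's slope on library spread. That slope came from all Control libraries. The treatment difference over weeks 4 to 10 had a Pearson r of 0.712 across genes with that slope, and week 4 had 0.608. With all libraries these values were -0.562 and -0.843, so the fit without spread below 2 still followed spread, with the opposite sign. Without spread below 3 they were -0.245 and -0.012. No such value was computed for week 6.

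Between the arms, 0 genes were called at week 0 and 0 at week 2 by limma, with 582 and 1051 at an unadjusted p below 0.05. At week 4, 8589 genes were called, 3426 higher and 5163 lower in iPAAG horses. Without the libraries of spread below 2, which left 3 iPAAG libraries, 16 genes were called, all lower. With all libraries the count was 5637 without horse 7. At week 8, 133 genes were called, 37 higher and 96 lower, while 822 were called without the libraries of spread below 2 and 8 without those of spread below 3. The week 8 count was 0, 0, 7, 12, 14, 19, 21 and 62 without horses 5, 16, 17, 15, 11, 6, 8 and 13, and 245 and 321 without horses 2 and 10. At weeks 6 and 10, 0 genes were called, with 1824 and 6874 at an unadjusted p below 0.05. The week 10 count became 6745 without horse 5, 7450 without horse 13 and 7730 without horse 14. In total 8635 genes were called between the arms in at least 1 week after injection, 39.9% of them higher. The share was 16.5% with voom weights (907 higher and 4595 lower) and 17.6% with spread as a covariate (551 and 2579). With array weights it was 51.1% (8077 and 7714), so the split depends on the model.

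**Figure D4:**
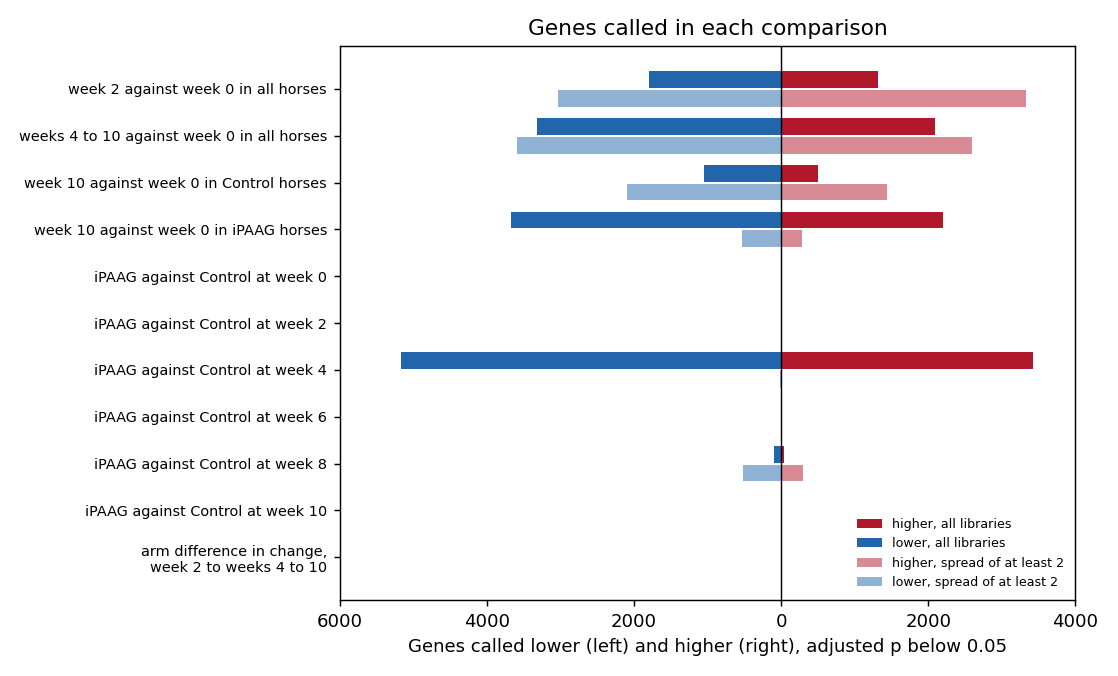
Number of genes called in each comparison: bars to the right are genes called higher and bars to the left genes called lower, with an adjusted p below 0.05. Dark bars are from all 93 libraries and pale bars from the 70 of spread at least 2; the week 4 difference between arms went from 8589 genes to 16, and week 2 against week 0 from 3112 to 6362.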

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

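Chosen after the results were seen were the tests of the background, of depth and of the week 4 response horse by horse. So were the tests of library spread between the arms and of horse 11, and the fits without libraries of low spread. Bounds for the ratio of week 4 differences, the change shared by both arms and the other splits were set before their results were seen. The ratio and the shared change rest on the fit without low-spread libraries, whose cut came from the data, so they were not wholly preset.

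In 36 group-and-measure sets, 10 library values stood apart from the rest of their group by Dixon's ratio, where chance gives about 1 in 20. Control horse 11 at week 0 and Control horse 10 at week 2 stood apart in both spread and reads. The measures come from the same libraries, so the sets are not independent and 1 in 20 is only a rough guide. The spread was high in Control horse 11 at week 0 (4.21, nearest library 3.68). It was low in Control horse 10 at week 2 (1.34, nearest 3.26), Control horse 13 at week 4 (2.94, nearest 3.38), iPAAG horse 14 at week 0 (1.65, nearest 2.82) and iPAAG horse 03 at week 8 (1.48, nearest 3.12). Reads were few in Control horse 11 at week 0 (17431476), Control horse 10 at week 2 (5355869) and iPAAG horse 14 at week 2 (7877238). A single gene took 44.8% of the reads of Control horse 11 at week 8, against at most 4.92% in the rest of that group. The top gene of iPAAG horse 17 at week 8 took 4.50%, against at most 2.58%.

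The change from week 2 to week 4 differed between the arms for 3633 genes, a tested difference between groups, and 8589 genes were called between the arms at week 4; lower depth alone is argued against, since the 4 iPAAG libraries of spread below 2 at week 4 each held at least 15792 genes at the common depth of 1737741 reads, while no Control library of week 4 held more than 14627. A response that all treated horses share is also argued against as the whole of the pattern: for genes called without a horse, that horse's own median difference in the called direction was 0.04 to 0.22 in 3 of 7 iPAAG horses (8, 12 and 17, upper quartile at most 0.62), where the fit to the remaining horses gave 1.66 to 1.67, and the second lowest ratio was 0.110. These 3 are the horses of spread at least 2, so this is the same division of the horses as in the fit without low-spread libraries (ratio 0.156) and no separate evidence, and the other 4 horses had medians of 1.79 to 2.52. An even background of reads over all genes in some libraries stays open. The week 4 differences had a Pearson r of -0.921 across genes with each gene's slope on library spread in Control horses. Between arms at week 10 r reached -0.970, where 0 genes were called by limma and 6874 had an unadjusted p below 0.05. Such an r shows that the differences go with library spread, not what lowered the spread, so it does not decide about a background. A response in part of the horses, or a smaller shared one, stays open, as does whether the gel itself lowers library spread: the change in spread did not pass the test between arms (exact permutation p = 0.547941, 8 horses each), which does not show that it was alike, and the iPAAG arm had the lower mean spread already at week 0 (3.07 against 3.53, p = 0.0418, adjusted p = 0.136).

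The week 10 change in iPAAG horses, with 5866 genes, had an r of -0.933 across genes with that slope. Of the iPAAG libraries, 6 of 8 had low spread at week 10 and 1 of 8 at week 0. Here too r shows that the changes go with library spread, not what lowered it. The 828 genes called in the fit without the low-spread libraries are consistent with a change after surgery that both arms share, since 99.5% of them had the same sign in Control horses. Of these, 347 were among the 5866 in the same direction, so the other genes of the 5866 stay open. With 2 iPAAG libraries left at week 10, these tests do not bear on an effect of the gel at that week.

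The 133 genes called between arms at week 8 stay open. The differences between arms at week 8 had an r of 0.389 across genes with the slope on spread, and 0.517 without the low-spread libraries. Neither value decides about a background. Without the Control library of horse 11, where a single gene took 44.8% of reads, 19 genes were called, but leaving out any of 6 other horses (5, 6, 8, 15, 16 or 17) left between 0 and 21, so that library cannot be told apart from other horses as the source.

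Regrouping the same samples in 100 ways, the real grouping included, tested chance. For week 2 against week 0, 1 of 100 splits, the real one with 3112 genes, called as many, and the highest of the others called 678. For weeks 4 to 10 against week 0, 1 of 100 did, the real one with 5422, and the highest other called 1. For week 10 in Control horses, 1 of 100 did, with 1551 against 547, so chance can be excluded for these results at this threshold. Such splits do not separate a change of the cells over weeks from a change in library spread over weeks. Between arms after injection 1 of 100 splits reached 8635 genes, with 7707 as the highest other, and for the single-week treatment differences 2 of 100 reached 3633, with 5185 as the highest other. Few splits reached either count, and both shares were under the bound set before the results were seen. The highest other passed 3633 for the treatment differences and came near 8635 for the arms. On that ground, which was not part of the bound, chance is not treated as excluded for either. For the arms, 7404 genes were called by the second highest other split and 19 others called any gene, while for the treatment differences the second highest other called 1 gene. Chance cannot be excluded for week 10 in iPAAG horses (5 of 100, 5866 against 11277), single weeks against week 0 (5 of 100, 9346 against 12181) or single weeks against week 2 (6 of 100, 9626 against 12379). For the treatment difference over weeks 4 to 10 and for the arms at weeks 0 and 2 the count by limma was 0, which any split reaches (100 of 100), so the splits say nothing about chance there, with 2812 and 5 genes as the highest others.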

How the results depend on the processing

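The fits without libraries of low spread, with spread as a covariate and without 1 Control library were added after the data were seen; a count is described as moved when it differs by more than 1.5 times. The 16 single-gene values kept their sign in all 512 refits; 30 refits lost a call and 1 gained it, all at week 10. Leaving horse out as a block moved no count. Horse as a fixed block moved none either, and cannot test arms at a single week. Both ended the call of ENSECAG00000018814 at week 10 in Control horses (adjusted p = 0.0517 and 0.0508).

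Array weights moved all counts: 6650 for week 2 against week 0, 10484 for weeks 4 to 10 against week 0, 5119 and 12641 for week 10 in Control and iPAAG horses, 10320 for the treatment difference over weeks 4 to 10 and 14460 at single weeks, 15110 between arms at weeks 4 to 10 and 2981 at weeks 0 and 2, and 15562 and 15483 for single weeks against weeks 0 and 2. Spread as a covariate gave 6328 for week 2, 4033 and 1058 for week 10 in Control and iPAAG horses, 2358 for the treatment difference over weeks 4 to 10, and between arms 3130 at weeks 4 to 10 and 1 at weeks 0 and 2. Without spread below 2, the counts were 6362 for week 2, 3538 and 828 for week 10 in Control and iPAAG horses, 146 for treatment differences at single weeks, 838 between arms at weeks 4 to 10 and 5767 for single weeks against week 2. Without spread below 3 these were 6527, 2749, 1053, 163, 24 and 4567, with 2 between arms at weeks 0 and 2. Voom weights gave 3870 for week 10 in iPAAG horses, 2349 for treatment differences at single weeks and 5502 between arms at weeks 4 to 10. Fitting only the groups compared gave 2560 for week 10 in iPAAG horses and 0 treatment differences at single weeks. Quantile normalisation gave 884 for week 10 in Control horses. The cause was not tested.

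Leaving out each horse gave 2596 to 3377 genes for week 2 against week 0 and 3903 to 6947 for weeks 4 to 10. For week 10 in Control horses it gave 710 (without horse 13) to 1763, with 841 without horse 9. For week 10 in iPAAG horses it gave 2586 (without horse 12) to 9948 (without 14), with 2626, 2696, 2966 and 2870 without horses 3, 6, 7 and 17. The treatment difference over weeks 4 to 10 ran from 0 to 2903 (without 14). At single weeks it ran from 0 (without 5, 6, 7 or 10) to 6506 (without 14), with 5666 without 12 and 2345 without 16. Between arms the counts were 5716 (without 7) to 10938 at weeks 4 to 10, and 0 to 7 (without 9) at weeks 0 and 2. Single weeks gave 5670 (without 7) to 12469 against week 0, with 5941 without 6, and 5096 (without 7) to 12922 against week 2.

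Quantile normalisation put the median of all genes at -0.26 for week 10 in iPAAG horses (deposited: -0.03), and median centring put it at 0.11 for week 2 against week 0 (deposited: 0.00). The gene list alternatives were not run. Depth limits low genes: ENSECAG00000007588 had a median of 5.5 reads at week 0, so its rise depends on the 0.5 reads added.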

Other observations

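The test of the flat profile below was chosen after the libraries were seen and is described with values only. Among 541 genes nearly absent from libraries of wide spread, the lowest-spread library of each of 12 horses ranked the genes alike, with a median Spearman rho of 0.92 between horses (0.83 to 0.97). Over all 15838 genes the same libraries had a median rho of 0.90 with each other and of 0.56 with the week 0 library of their own horse, over 10 horses. Week 0 libraries of different horses had a median rho of 0.95. The slopes of genes on library spread had a Pearson r of 0.98 between Control and iPAAG horses. Control libraries of week 4 thinned to 3954618 reads kept a spread of 2.90 to 3.33.

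The changes from week 0 were also compared between the arms at later weeks without the libraries of spread below 2. Across genes, Pearson r between the arms was 0.67 at week 2, 0.43 at week 4, 0.29 at week 6, 0.33 at week 8 and 0.66 at week 10. With all libraries the values in that order were 0.71, 0.27, 0.81, 0.30 and 0.77. Without spread below 3 they were 0.61, 0.50, 0.30, 0.54 and 0.68, so the course over weeks depends on the libraries kept. In the fit without spread below 2, of 1996 genes higher at week 2 in Control horses, 97.8% were higher at week 2 in iPAAG horses and 70.5% at week 10. Of 2220 genes higher at week 2 in iPAAG horses, 98.4% were higher at week 2 in Control horses and 91.6% at week 10. That fit kept 3 iPAAG libraries at week 4 and 2 at week 10, and left out 2 of 8 Control libraries at week 10. The 70.5% and 91.6% thus rest on unequal numbers of libraries, and their difference was not tested.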
